A study of Mus musculus with 23 samples.

How the data were processed

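RNA was measured in 23 mouse libraries of cells sorted as CD138-positive and B220-negative, the surface phenotype of plasma cells. Per the labels, 3 control libraries came from bone marrow of mice with the IgG1-Cre transgene alone. The other 20 libraries came from recipients of transplanted myeloma cells. Of these, 4 donor lines (VQ-D1, VQ-D2, VQ-D4 and VQ-D5) combine a Vκ*MYC transgene with an oncogenic Nras allele switched on by Cre. The donor line t-VK12653 carries Vκ*MYC alone. Each line has 4 libraries, from bone marrow, spleen, lymph node or liver. The labels do not say which libraries of a line share a recipient. Recipient numbers appear only in the names of the deposited tables and were used only in alternative fits. The p-values of comparisons between lines therefore measure the spread between libraries of single donors, not between donors of a genotype.

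Per the labels' protocols, total RNA was extracted with a micro-scale column kit and made into libraries with a stranded total RNA kit for picogram inputs. STAR, featureCounts and DESeq2 and the builds GRCm38 and mm10 are named in the submitters' processing notes, without versions or settings. The annotation and the strand setting of the counting are not given in the sources used here. Per the file headers, each deposited table holds a count, an FPKM value and a TPM value for 24063 gene symbols. The count column holds whole, unnormalized read counts made by the authors. The FPKM column holds values scaled to gene length and depth by the authors, and the TPM column holds length-scaled values as deposited. Neither FPKM nor TPM was used for a test. No immunoglobulin segment and no mitochondrial transcript is among the listed symbols. Immunoglobulin clonality, planned before the data were examined, and a mitochondrial RNA quality list were therefore not analysed here. Reads from overlapping or antisense genes and from pseudogenes of ribosomal and glycolytic genes cannot be told apart in such counts.

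Total counts ranged from 2685579 to 10047314 per library (median 4627000), and 13394 to 17188 genes had at least 1 count. The 3 control libraries averaged 3166000 counts and the line averages lay between 4522000 and 6731000. The ribosomal precursor transcript Rn45s took 16.4% to 27.3% of counts. No pair of libraries of a group agreed within sampling noise: chi-square per degree of freedom over genes was 4.57 to 22.3. A count of 0 over a whole group was bounded with a floor of 3 counts, which is 0.305 CPM over the 3 controls and 0.108 to 0.181 CPM over the 4 libraries of a line. The fit of line sums has its own scaling, and its floor over the 3 controls is 0.295 CPM. Where a group held 1 to 3 reads of a gene, the ratio is given with a 95% counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

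Analysis was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The main test was edgeR's robust quasi-likelihood F-test on counts, with TMM scaling, the filterByExpr filter (count minimum 10, total minimum 15) and Benjamini-Hochberg adjustment. Genes were called at an adjusted p under 0.05. VQ was compared with control on counts summed per donor line (4 line sums against 3 control libraries). All control libraries are bone marrow while the sums pool several tissues, so this fit has no tissue term. It does not separate site from genotype, and bone marrow libraries alone were fitted as an alternative. All other comparisons came from 1 fit of the 23 libraries with terms for group and tissue. A gene was line-specific when it passed the threshold in the same direction against each of the other 3 VQ lines. Standard errors (SE) of log2 fold changes came from the same fits. Values in CPM are TMM-scaled. Log2 CPM for similarity used a prior count of 2 and the 1000 most variable genes.

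There were 34 gene lists fixed before the data were examined. They covered plasma cell and B cell identity, antigen presentation, growth and signalling pathways, metabolism, myeloma genes, and markers of other cell types. Lists with 5 or more tested genes were tested with camera on voom values at a preset inter-gene correlation of 0.01, and again with the correlation that camera estimates. All 168 list calls at the preset correlation were lost with the estimated one, so that p is printed beside each list. Named genes followed a rule fixed before the data were examined. It took Nras and Myc, then for the control and genotype comparisons the 8 highest and 8 lowest fold changes among genes whose groups did not overlap, with adjusted p under 0.05 and at least 10 CPM in the higher group. For each VQ line it took the 5 line-specific genes per direction with the largest smallest difference, for each tissue comparison the 5 highest and 5 lowest, and up to 4 members of each called list. List members could also be named for their level. Predicted genes, small RNA and sex-linked genes were left out of the picks by fold. Sex-linked was applied to the members of the list of sex-linked genes, so other X-linked genes could be picked. Some picks of this rule are not reported here and were not replaced. Gene positions are from the RefSeq annotation of GRCm38.p6.

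The model was tested on simulated counts with 200 changed genes. In the fit of 23 libraries it recovered 75% to 96.9% of genes changed by 4-fold and 14.8% to 42.9% of those changed by 1.5-fold. For the VQ line sums against control it recovered 14.1% at 4-fold and 0% at 1.5-fold and 2-fold. Unchanged genes made up 0.752% (lymph node against spleen) to 7.03% (VQ-D1 against VQ-D4) of calls in the fit of 23 libraries. They made up 10% for the line sums, from 1 unchanged gene called. The simulated libraries were drawn as independent, so spread shared by libraries of a donor or recipient was not simulated. These shares therefore do not cover it. Alternatives were DESeq2, RLE scaling, no filter, other units and blocks, and leaving out each library. Added after the data were seen were a fit without abundant non-coding RNA, a fit without VQ-D1 replicate 1 and VQ-D4 replicate 2 together, and tissue effects within single lines. Control replicate 2 was singled out after the data were seen, and the fit without it is among the planned ones.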

Results

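Total RNA was sequenced from sorted plasma cells of 3 control mice and from myeloma cells of 5 transplanted donor lines, with 4 libraries per line. By the recipient numbers, the libraries of a line come from 2 recipients of 1 donor. For a line, n = 4 therefore counts libraries, not animals. The control, VQ-D1, VQ-D4, VQ-D5 and t-VK12653 groups include bone marrow libraries. VQ-D2 was sampled from spleen and lymph node. VQ-D4 contributed 1 library each from bone marrow, liver, spleen and lymph node. Total counts per library ran from 2685579 to 10047314. The series title speaks of a division of VQ myeloma into clusters, and the labels do not assign lines to them.

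Both genes of the engineered genotype were measured first. Myc, the transcription factor that the Vκ*MYC transgene encodes, was at 43.0 ± 14.2 CPM (SD, n = 3) in controls. It reached 591.2 ± 77.2 CPM in VQ-D1, 3473 ± 62.5 in VQ-D2, 1373 ± 204 in VQ-D4, 1161 ± 105 in VQ-D5 and 6534 ± 252 in t-VK12653 (SD, n = 4 each). Nras, which encodes a RAS GTPase upstream of MAPK signalling, was at 32.2 ± 0.848 CPM in controls. Its level was 42.3 ± 4.59 CPM in VQ-D1, 87.3 ± 9.19 in VQ-D2, 51.0 ± 1.95 in VQ-D4, 124.2 ± 12.1 in VQ-D5 and 43.5 ± 5.25 in t-VK12653. Nras lies on chromosome 3 from 103058285 to 103067914 and Myc on chromosome 15 from 61985341 to 61990361. How reads of the transgene were counted is not given in the sources used here.

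**Figure D1:**
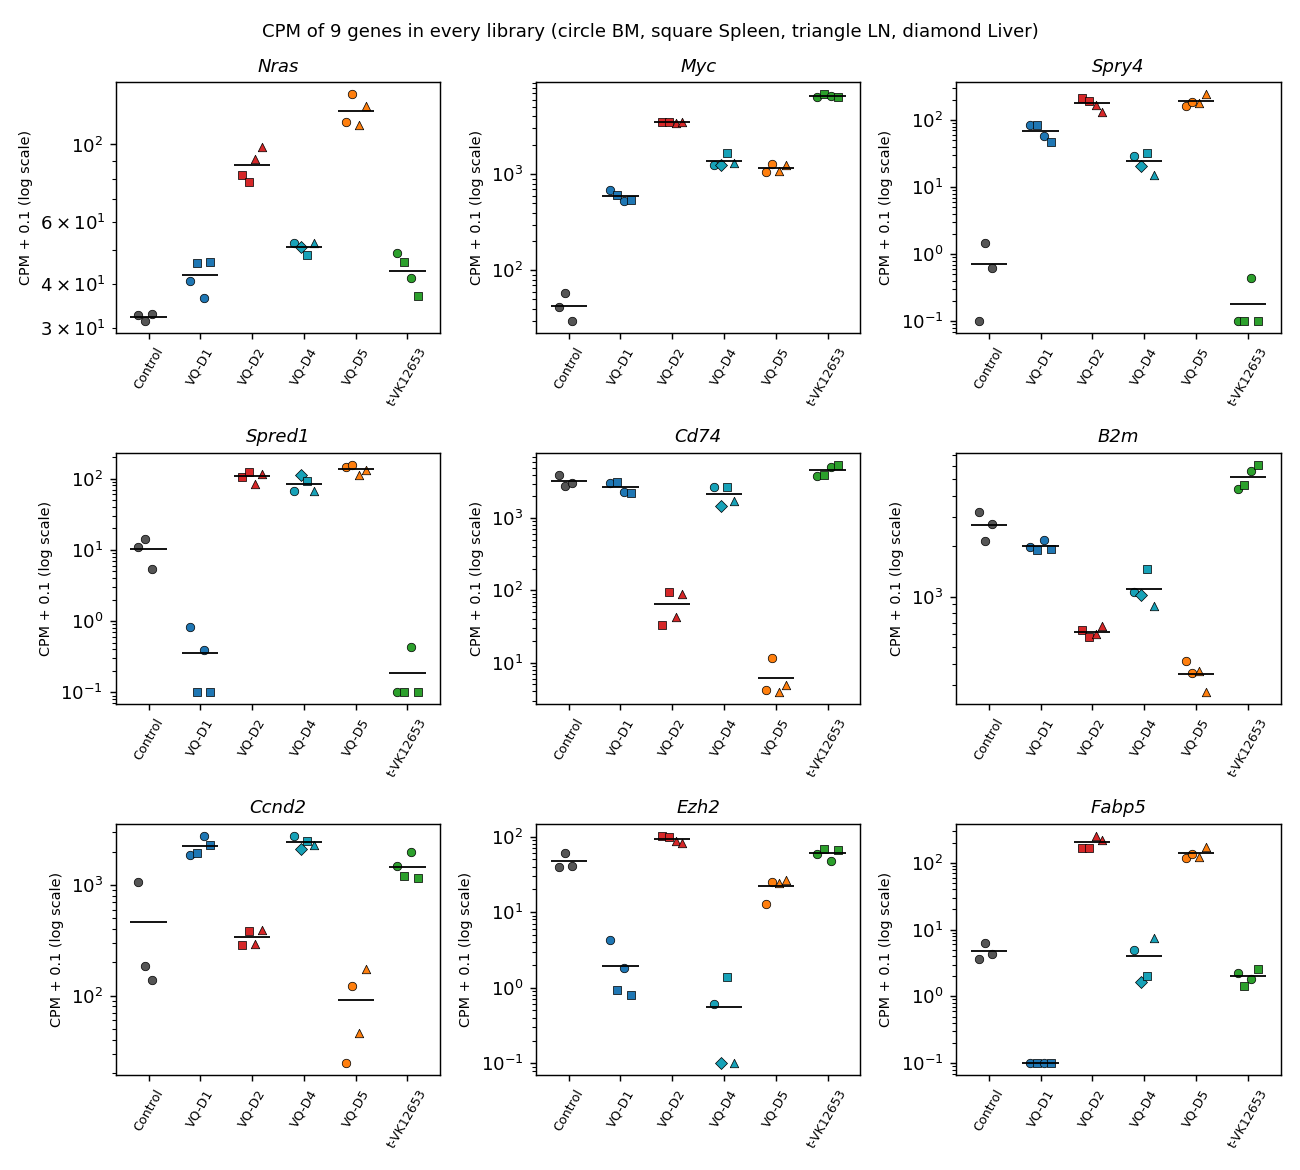
CPM of 9 genes in every library on a log scale after adding 0.1, with 1 point per library and a bar at the group mean. Myc is lowest in the 3 controls, and Fabp5 is highest in VQ-D2 and VQ-D5.

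The similarity of libraries addressed how the donor lines relate. Every tumour library was closest to its own line: 20 of 20 correlated best with another library of that line over the 1000 most variable genes. Among the VQ lines, VQ-D1 lay nearest to VQ-D4 and VQ-D2 nearest to VQ-D5 for 16 of 16 libraries. The mean correlation was 0.431 between VQ-D1 and VQ-D4 and 0.568 between VQ-D2 and VQ-D5, against 0.118 between VQ-D1 and VQ-D2 and 0.198 between VQ-D4 and VQ-D5. The MYC-only line t-VK12653 correlated at 0.37 with VQ-D1 and 0.395 with VQ-D4, and at 0.02 with VQ-D2 and 0.0126 with VQ-D5. The first principal component held 36.1% of the variance and the second 21.8%. These correlations are across genes, which are not independent replicates, and no test was made between lines grouped this way.

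**Figure D2:**
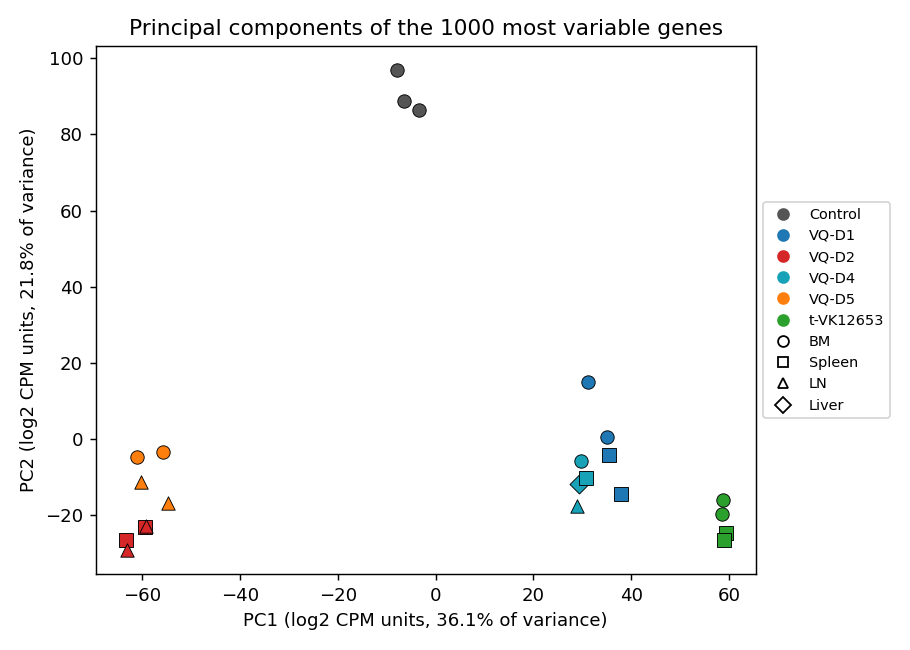
Principal components of log2 CPM over the 1000 most variable genes, with 1 point per library, coloured by group and shaped by tissue. VQ-D2 and VQ-D5 lie at PC1 from −63.36 to −54.75, while VQ-D1 and VQ-D4 lie at 28.98 to 38.01.

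Compared with control plasma cells, the VQ lines had more RNA of MYC target and ribosomal protein genes and less of B cell identity and MHC class II genes. These list calls were made at a preset correlation, and with an estimated correlation the adjusted p was 0.234, 0.155, 0.13 and 0.242 in that order. Of 30 MYC targets, 26 rose and none fell (26 adjusted over the list alone), among them Npm1, a nucleolar chaperone, with a log2 fold change of 2.65 (SE 0.397, adjusted p = 0.00622). Of 38 cytosolic ribosomal protein genes 35 rose (36 adjusted over the list alone), and of 18 B cell identity genes 10 fell (12 adjusted over the list alone). Blk, a B cell kinase, was at 45.8 ± 11.5 CPM in controls (SD, n = 3) and had 1 read over the 4 line sums, a ratio of 4160 with a counting interval of 744 to 165000. In all, edgeR called 3192 of 13870 genes, 1906 higher and 1286 lower. The higher share was 59.7% with TMM and 50.6% with RLE scaling, which shifted all genes by −0.115 in the median. Myc was higher by 5.40 on the log2 scale (SE 0.748, adjusted p = 0.00556) and Nras by 1.38 (SE 0.4, adjusted p = 0.0448).

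The lists higher in the VQ lines were as follows. The camera adjusted p was 5.63e-13 for MYC targets (adjusted p = 0.234 with an estimated correlation) and 6.41e-19 for ribosomal proteins (adjusted p = 0.155 with an estimated correlation). Proteasome genes were higher in 22 of 31 (28 adjusted over the list alone), with camera adjusted p = 8e-10 and adjusted p = 0.234 with an estimated correlation. Oxidative phosphorylation genes were higher in 26 of 34 (26 adjusted over the list alone), with camera adjusted p = 2.89e-10 and adjusted p = 0.13 with an estimated correlation. Glycolysis genes were higher in 7 of 16 (8 adjusted over the list alone), including Ldha at 2.28 on the log2 scale (SE 0.39, adjusted p = 0.00872). The glycolysis list had camera adjusted p = 0.00234 and adjusted p = 0.202 with an estimated correlation. Cell cycle genes were higher in 14 of 32 and in 29 adjusted over the list alone, with Cdc20, an activator of the anaphase-promoting complex, up by 3.08 (SE 0.766, adjusted p = 0.0277). The cell cycle list had camera adjusted p = 1.04e-07 and adjusted p = 0.367 with an estimated correlation. Orthologues of human high-risk myeloma score genes were higher in 12 of 29 (21 higher and 1 lower adjusted over the list alone), with camera adjusted p = 2.01e-05 and adjusted p = 0.367 with an estimated correlation. Targets of p53 were higher in 7 of 16 (8 adjusted over the list alone), with camera adjusted p = 0.0101 and adjusted p = 0.367 with an estimated correlation. Cholesterol synthesis genes were higher in 5 of 19 (7 adjusted over the list alone), with camera adjusted p = 0.00647 and adjusted p = 0.142 with an estimated correlation.

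The lists lower in the VQ lines were as follows. B cell identity had camera adjusted p = 3.46e-09 and adjusted p = 0.13 with an estimated correlation. MHC class II genes were lower in 6 of 10 (6 adjusted over the list alone), led by H2-Aa at −6.79 (SE 1.03, adjusted p = 0.00648). That list had camera adjusted p = 0.00012 and adjusted p = 0.242 with an estimated correlation. Plasma cell identity split, with 2 of 22 genes higher and 5 lower, the same numbers adjusted over the list alone. Igj, the immunoglobulin joining chain, fell by 5.73 on the log2 scale (SE 1.08, adjusted p = 0.0117), while Fkbp11, a secretory pathway isomerase, rose by 3.08 (SE 0.386, adjusted p = 0.0047). This list had camera adjusted p = 0.024 and adjusted p = 0.388 with an estimated correlation, and its call ended without Control replicate 1 (0.0866), without VQ-D2 (0.112), in bone marrow alone, which has no VQ-D2 library (0.139), and without a filter (0.3). NF-kB targets were lower in 6 of 17 (8 adjusted over the list alone), with camera adjusted p = 5.02e-07 and adjusted p = 0.234 with an estimated correlation. Immune checkpoint genes were lower in 6 of 16 and higher in 2 (9 lower and 2 higher adjusted over the list alone), with camera adjusted p = 0.000118 and adjusted p = 0.13 with an estimated correlation. Cd200, an inhibitory surface ligand, fell by 8.19 (SE 0.874, adjusted p = 0.00328) and Cd276 rose by 6.64 (SE 1.62, adjusted p = 0.0265). Homing and adhesion genes were lower in 7 of 21 and higher in 1 (9 and 1 adjusted over the list alone), with camera adjusted p = 0.000225 and adjusted p = 0.143 with an estimated correlation. Interferon response genes were lower in 4 of 24 and higher in 1 (4 and 1 adjusted over the list alone), with camera adjusted p = 0.0037 (0.109 without a filter) and adjusted p = 0.388 with an estimated correlation. Myeloma translocation and cyclin D genes were lower in 4 of 8 (5 adjusted over the list alone), with camera adjusted p = 0.0101 and adjusted p = 0.183 with an estimated correlation. That call ended without a filter (0.0708) and for the mean of the lines in the fit of all libraries (0.0529). Dissociation and stress genes were lower in 5 of 16 (5 adjusted over the list alone), with camera adjusted p = 0.000529 and adjusted p = 0.367 with an estimated correlation.

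Markers of other cells moved with these groups. The controls are all bone marrow, while the line sums pool several tissues. Within tumour lines, neutrophil genes were lower in spleen and lymph node than in bone marrow (medians −3.15 and −4.08 on the log2 scale). All 17 neutrophil genes were lower in the VQ lines (17 adjusted over the list alone; camera adjusted p = 7.4e-13, adjusted p = 0.188 with an estimated correlation). Their summed level was 3337, 9271 and 3783 CPM in the 3 control libraries and 4.58 to 1243 CPM in tumour libraries. T and NK cell genes were lower in 12 of 15, erythroid genes in 11 of 12, and monocyte and macrophage genes in 9 of 15 (13, 11 and 10 adjusted over the list alone). Their camera adjusted p values were 5.54e-09, 1.08e-06 and 6.95e-07, and with an estimated correlation the adjusted p was 0.13, 0.234 and 0.188. Megakaryocyte, mast cell and basophil genes were lower in 7 of 10 (8 adjusted over the list alone; camera adjusted p = 2.84e-06, adjusted p = 0.188 with an estimated correlation). Dendritic cell genes were lower in 3 of 11 and higher in 1 (3 and 1 adjusted over the list alone; camera adjusted p = 0.0287, adjusted p = 0.188 with an estimated correlation). The dendritic cell call ended without VQ-D2 (0.0597) or VQ-D5 (0.0688), without VQ-D1 replicate 1 and VQ-D4 replicate 2 together (0.0508), in bone marrow alone, so again without VQ-D2 (0.191), without a filter (0.0708) and for the mean of the lines (0.084). Sex-linked genes were lower in 4 of 5 (5 adjusted over the list alone; camera adjusted p = 3.09e-05, adjusted p = 0.13 with an estimated correlation). Y-linked Ddx3y was at 92.3 ± 44.0 CPM in controls (SD, n = 3) and at or below 0.166 CPM on average in every tumour line. Every comparison of tumour lines with control is therefore unmatched for Y-linked RNA, and no fit had a term for sex. Camera made no call for MHC class I presentation (0 of 11 genes past the threshold, adjusted p = 0.279), MAPK output (6 of 19 higher and 1 lower, adjusted p = 0.21), the unfolded protein response (3 of 22 higher and 2 lower, adjusted p = 0.584) or BCL2 family genes (1 of 17 higher and 2 lower, adjusted p = 0.279). It made none for myeloma drug targets (3 of 22 higher and 6 lower, adjusted p = 0.125), PRC2 and histone methyltransferases (2 of 21 higher and 1 lower, adjusted p = 0.659) or endothelial and stromal markers (1 of 9 lower, adjusted p = 0.114). Adjusted over the list alone the higher and lower counts were 0 and 0, 6 and 1, 3 and 2, 0 and 2, 5 and 6, 1 and 0, and 0 and 1 for these 7 lists.

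Among genes whose values did not overlap between the groups, Strc, which encodes stereocilin, had 0 reads in controls and 48.4 ± 31.4 CPM in the line sums (SD, n = 4), at least 164-fold higher over the group floor of 0.295 CPM in this fit. It stood at 1.66 CPM in VQ-D1 and between 54.7 and 63.7 CPM on average in the other lines. Strc overlaps Ckmt1 on chromosome 2, and these genes can share reads. Slc47a1, a drug and toxin exporter, was at least 71.4-fold higher and Atp6ap1l at least 65.1-fold higher. Spats2 had 1 control read and a ratio of 1120 with a counting interval of 201 to 44300. Spry4, a feedback inhibitor of MAPK signalling, rose by 7.71 (SE 1.18, adjusted p = 0.00655), Lamb1 by 7.43 (SE 0.907) and Fam20a by 7.20 (SE 1.21). Fkbp10, with 3 control reads, had a ratio of 211 and a counting interval of 72.3 to 1020. On the low side, Cd79a, part of the B cell receptor, fell by 9.57 (SE 0.594, adjusted p = 0.0011), Serpina3g by 9.47, Cd83 by 9.39, Serpina3f by 9.08, Trib2 by 8.82, Dntt by 8.80 and Parm1 by 8.49. Dntt (SE 1.51) was uneven between the control libraries, at 43.2 ± 54.9 CPM (SD, n = 3). The count of genes fell to 1221, 1148 and 1226 without Control replicates 1, 2 and 3, and was 2027 with bone marrow libraries alone, which also leaves out VQ-D2 (2325 without VQ-D2 in all tissues), and 7786 for the mean of the lines in the fit of all libraries. The Nras call ended with RLE scaling (1.27), without abundant non-coding RNA (1.31), in bone marrow alone and so without VQ-D2 (1.20), and without VQ-D2 (1.21), VQ-D5 (0.947) or any control (1.30 to 1.40); the Strc call ended without a filter (12.4), without VQ-D2 or VQ-D5 (12.1 each) and without any control (12.6 each), and the Blk call in the mean of the lines (−9.98).

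The comparison of t-VK12653 with control covered the MYC-only genotype in 1 donor. Ribosomal protein genes were higher in 34 of 38 and MYC targets in 26 of 30, with 1 MYC target lower. B cell identity genes were lower in 16 of 17 and interferon response genes in 18 of 20. The counts adjusted over the list alone were the same for these 4 lists. Camera gave adjusted p of 2.53e-16, 8.53e-08, 1.97e-06 and 5.02e-05 for these lists in turn, and adjusted p = 0.16 with an estimated correlation for each. Gpr158, an orphan receptor, was at 160.4 ± 14.4 CPM (SD, n = 4) against 0 control reads, at least 527-fold higher. Overall edgeR called 7320 of 12867 genes, 3700 higher and 3620 lower.

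Further genes had few or no reads on one side. Bche was at least 280-fold, Lin28b at least 177-fold, Nxf3 at least 135-fold, Slc7a15 at least 116-fold and Slc47a1 at least 106-fold higher in t-VK12653. Sis, the intestinal sucrase-isomaltase, had 1 control read and a ratio of 2730 with a counting interval of 490 to 108000. Spats2 had a ratio of 1700 (305 to 67300). In the other direction Serpina3g was at least 645-fold, Btla at least 544-fold, Faim3 at least 434-fold, Akap2 at least 353-fold and Ctla4 at least 347-fold lower. Egr1, an immediate early gene, had 2 reads in t-VK12653 and a ratio of 4250 (1180 to 35100), and Cd93 had 1 read and a ratio of 4630 (831 to 183000). Neutrophil genes were lower in 17 of 17 (17 adjusted over the list alone), with camera adjusted p = 6.65e-06 and adjusted p = 0.365 with an estimated correlation. T and NK cell genes were lower in 9 of 10 and erythroid genes in 10 of 11 (10 each adjusted over the list alone), and monocyte and macrophage genes were lower in 10 of 13 and higher in 2 (10 and 2 adjusted over the list alone). For these lists the camera adjusted p was 0.000701, 0.00452 and 0.00942, and adjusted p = 0.16, 0.447 and 0.365 with an estimated correlation. Sex-linked genes were lower in 5 of 5 and dissociation and stress genes in 7 of 16 (5 and 7 adjusted over the list alone), with camera adjusted p = 0.00938 and 0.0178, and adjusted p = 0.16 and 0.48 with an estimated correlation. The stress call ended without t-VK12653 replicate 1 (0.0594).

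The contrast of the 4 VQ lines with t-VK12653 sets the combined genotype against MYC alone, with 1 donor on the MYC side. MAPK output genes were higher in 10 of 18 and lower in 2 (10 and 2 adjusted over the list alone). Of these, Spry4 was at 115.3 ± 77.5 CPM in VQ (SD over 16 libraries of 4 donor lines) and had 1 read in t-VK12653. The ratio for Spry4 was 1980 with a counting interval of 355 to 78100. MHC class I presentation genes were lower in 9 of 11 and higher in 1 (9 and 1 adjusted over the list alone), with B2m, the invariant class I subunit, lower by a log2 fold change of −2.56 (SE 0.116, adjusted p = 1.73e-13). NF-kB targets were lower in 11 of 16 (11 lower and 1 higher adjusted over the list alone), including Nfkb2 at −2.74 (SE 0.231, adjusted p = 1.79e-08). Camera adjusted p was 0.0283, 0.000673 and 0.00264 for these lists, with adjusted p = 0.733, 0.68 and 0.655 with an estimated correlation. The MAPK output call ended without t-VK12653 replicate 2 (adjusted p = 0.0657).

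Myc was lower in VQ by −2.25 on the log2 scale (SE 0.107, adjusted p = 1.81e-13), while 25 of 30 MYC targets were higher and 1 lower (25 and 1 adjusted over the list alone). Proteasome genes were higher in 25 of 31 and lower in 4, and cell cycle genes higher in 25 of 32 and lower in 3, each with the same counts adjusted over the list alone. High-risk score orthologues were higher in 19 of 29 and lower in 5 (19 and 5 adjusted over the list alone). Camera adjusted p was 7.98e-10 for MYC targets, 5.21e-06 for the proteasome, 5.4e-05 for the cell cycle and 0.000866 for the score genes. With an estimated correlation the adjusted p was 0.273, 0.273, 0.733 and 0.68. In all 7870 of 12867 genes passed, 3806 higher and 4064 lower in VQ. Dnajc15 was at least 299-fold, Syndig1l at least 255-fold, Sfmbt2 at least 235-fold and Alkbh3 at least 166-fold higher in VQ. Nes, the intermediate filament nestin, had 2 reads in t-VK12653 and a ratio of 2330 (644 to 19200), Crim1 a ratio of 1430 (395 to 11800) and Egr1 a ratio of 2270 (629 to 18800). Higher in t-VK12653 were Rfx6, a pancreatic and intestinal transcription factor, at 147.6 ± 10.6 CPM (SD, n = 4) and the class I-like gene H2-M10.1 at 408.1 ± 47.3 CPM. Fmr1nb, Prg3, Maoa and Bche were higher there too, at 227.4, 207.5, 30.1 and 85.5 CPM, and Hoxa7 had a ratio of 2280 (629 to 18900). The Egr1 call ended in limma voom with recipient as a random block, at 9.37.

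Pairwise comparisons of the VQ lines addressed how donors of 1 genotype differ. The fewest genes differed between VQ-D2 and VQ-D5 (4970 of 12867, 2396 higher in VQ-D2 and 2574 lower) and between VQ-D1 and VQ-D4 (5307, 2628 higher in VQ-D1 and 2679 lower). The other pairs gave 6601 genes for VQ-D1 against VQ-D2 (3195 higher, 3406 lower) and 7523 for VQ-D1 against VQ-D5 (3704 higher, 3819 lower). They gave 7337 for VQ-D2 against VQ-D4 (3782 higher, 3555 lower) and 7557 for VQ-D4 against VQ-D5 (3743 higher, 3814 lower). Fabp5, a fatty acid binding protein, was at 200.6 ± 44.2 CPM in VQ-D2 and 137.3 ± 24.5 in VQ-D5, against 0 reads in VQ-D1 and 3.94 ± 2.72 CPM in VQ-D4 (SD, n = 4 each). Ly6d, a lymphoid surface marker, went the other way at 534.3 ± 19.04 CPM in VQ-D1 and 259.4 ± 82.5 in VQ-D4, against 0.266 in VQ-D2 and 0.35 in VQ-D5. Cd74, the class II invariant chain, was at 2708 ± 493 and 2150 ± 654 CPM in VQ-D1 and VQ-D4 and at 65.1 ± 31.1 and 6.08 ± 3.76 in VQ-D2 and VQ-D5. With counts summed per recipient, VQ-D2 against VQ-D5 gave 3115 genes.

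Each line was also set against the mean of the other 3. A line is thus part of the reference of every other line. The contrasts are not independent, and opposite moves of a list in different lines are partly forced. In VQ-D5, 32 of 32 cell cycle genes, 27 of 30 MYC targets, 23 of 31 proteasome genes and 25 of 29 high-risk score orthologues were higher, and none of these lists had a gene lower. Adjusted over the list alone the counts were 32, 27, 24 and 26. Cdc20 was at 208.1 ± 13.97 CPM in VQ-D5 and 37.5 ± 3.79 in VQ-D1 (SD, n = 4). Camera adjusted p was 1.86e-11, 2.9e-10, 2.6e-06 and 4.19e-09, and adjusted p = 0.404, 0.176, 0.182 and 0.176 with an estimated correlation. NF-kB targets were lower in 12 of 16 (13 adjusted over the list alone; camera adjusted p = 0.000191, adjusted p = 0.201 with an estimated correlation). Tnfaip3, a feedback inhibitor of NF-kB, was at 0.979 CPM there and 123.7 in VQ-D1.

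In VQ-D4 the cell cycle genes were lower in 28 of 32, MYC targets in 23 of 30 with 2 higher, and ribosomal protein genes higher in 27 of 38 with 1 lower (29 lower, 23 lower and 2 higher, and 27 higher and 1 lower adjusted over the list alone). Camera adjusted p was 2.08e-10, 1.1e-08 and 1.43e-06, and adjusted p = 0.66, 0.569 and 0.822 with an estimated correlation. Stress genes were higher in 11 of 16 (11 adjusted over the list alone; camera adjusted p = 0.00188, adjusted p = 0.822 with an estimated correlation), with Egr1 at 1024 ± 518 CPM. In VQ-D1, p53 targets were higher in 13 of 16 (14 adjusted over the list alone), with Cdkn1a, a cyclin-dependent kinase inhibitor, at 60.3 ± 8.52 CPM against 2.56 ± 2.05 in VQ-D2. NF-kB targets were higher in 11 of 16 and MAPK output genes lower in 13 of 18 with 2 higher, the same numbers adjusted over the list alone. Camera adjusted p was 6.6e-05, 0.000116 and 0.00232 for these 3 lists, and adjusted p = 0.206, 0.387 and 0.387 with an estimated correlation. Spred1, a RAS pathway inhibitor, was at 0.257 CPM in VQ-D1 and 84.5 to 136.9 in the other VQ lines. Neutrophil genes were higher in 13 of 17 in VQ-D1 (14 adjusted over the list alone; camera adjusted p = 0.0241, adjusted p = 0.67 with an estimated correlation). Their summed level was 1243 CPM in replicate 1 of that line. The call ended without VQ-D1 replicate 1 (0.0759), without VQ-D4 replicate 1 (0.151) and without VQ-D1 replicate 1 and VQ-D4 replicate 2 together (0.0773). Monocyte and macrophage genes were higher in 10 of 13 in VQ-D1 (11 adjusted over the list alone; camera adjusted p = 0.00877, adjusted p = 0.387 with an estimated correlation). In VQ-D2, ribosomal protein genes were lower in 26 of 38 with 1 higher (27 and 1 adjusted over the list alone) and p53 targets lower in 12 of 16 with 1 higher (12 and 1 adjusted over the list alone). Camera adjusted p was 1.24e-06 and 0.00119, and adjusted p = 0.982 and 0.783 with an estimated correlation. The summed hepatocyte list was 3108 ± 427 CPM in VQ-D2 and 1391 ± 158 in VQ-D5, almost all from Trf, which encodes transferrin, at 3096 and 1382 CPM.

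**Figure D3:**
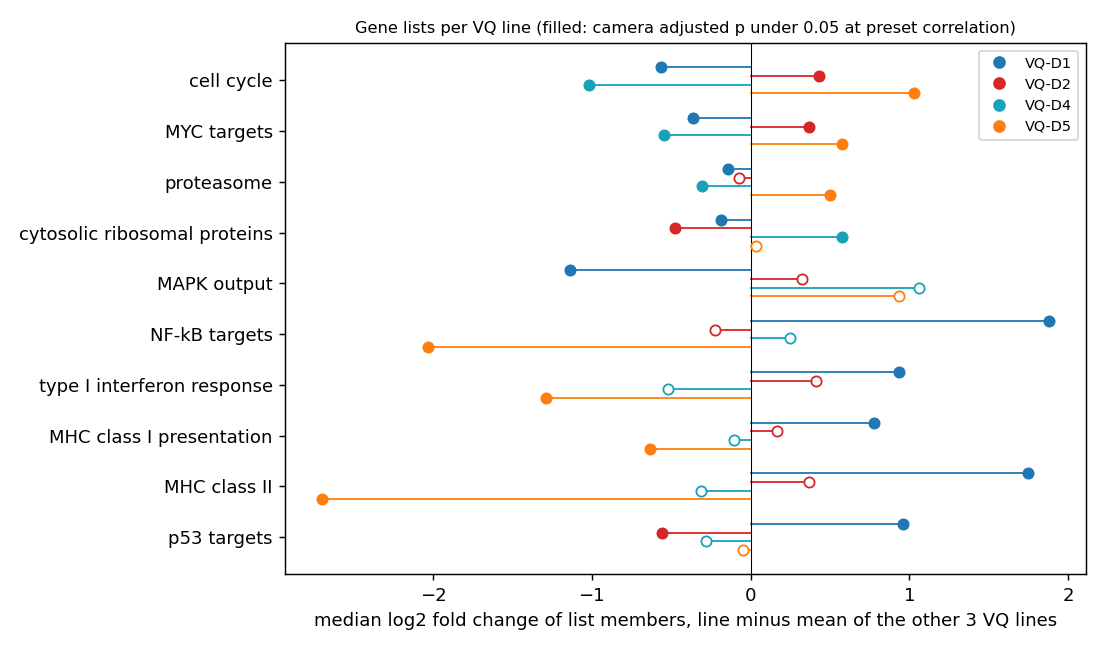
Median log2 fold change of the members of 10 of the gene lists, each VQ line minus the mean of the other 3, with filled points at a camera adjusted p under 0.05 for the preset correlation of 0.01. The cell cycle median is 1.03 in VQ-D5 and −1.02 in VQ-D4, and the calls are lost with an estimated correlation. Every line is part of the reference of the others, so opposite medians are partly forced.

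Line-specific genes numbered 724 higher and 911 lower in VQ-D1, 750 and 694 in VQ-D2, 1180 and 1126 in VQ-D4, and 1217 and 972 in VQ-D5. VQ-D2 had Tex101, a germ cell surface protein, at 307.1 ± 16.7 CPM and Mov10l1, a helicase of the germline piRNA pathway, at 312.5 ± 6.38 CPM (SD, n = 4), against 0.24 and 0.224 CPM in the other 3 lines. Sema3e was at 113 CPM in VQ-D2, and Prkaa2 and Prr19 had ratios of 2690 (481 to 106000) and 1480 (264 to 58400). In VQ-D4, Trap1a, a tumour rejection antigen, was at 383.7 ± 290 CPM, Cntn3 at 99.1 ± 113 and Klf4 at 39.7 ± 40.3, and Xlr4a was at least 364-fold higher. Fmr1nb had a ratio of 565 (192 to 2750). In VQ-D1, Esrp1, an epithelial splicing factor, was at 63.8 ± 9.69 CPM, Rbm24 at 67.3 ± 16.1, Pramef12 at 22.7 ± 2.63 and Arhgef16 at 19.5 ± 5.34, and Zfpm2 had a ratio of 1550 (428 to 12800). In VQ-D5, Scn11a, a sodium channel, was at 222 ± 78.9 CPM, Ptpn13 at 60.6 ± 11.1 and Dgkk at 36.4 ± 25.6. Tspan7 had a ratio of 4040 (723 to 160000) and Olfr157 one of 844 (288 to 4100). The Prr19 and Dgkk calls ended with DESeq2, at log2 fold changes of 8.46 and 8.74.

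Lower in VQ-D1 were Gabra4, by at least 559-fold, and Tmem18, by at least 223-fold, with ratios of 1060 (190 to 41900) for Dyrk2, 1350 (242 to 53300) for Slco5a1 and 926 (166 to 36600) for Zbtb10. Lower in VQ-D2 were Sccpdh, by at least 121-fold, Cryaa at 0.282 CPM against 27.0, and Emp2 with a ratio of 183 (62.4 to 887). Acsl3 and Utp14b, which overlap on chromosome 1 from 78657825 to 78667601 and can share reads, had ratios of 165 (56.3 to 801) and 199 (55 to 1650). Lower in VQ-D4 were Reln, an extracellular matrix protein, at 2.43 CPM against 678.4, Cd93 at 0.369 against 153.8, and Atp10a, Enpp3 and Evc2 with ratios of 1010 (181 to 39800), 3130 (561 to 123000) and 875 (242 to 7220). Lower in VQ-D5 were Cry1, a circadian repressor, at 0.179 CPM against 38.9, Mon1b at 0.292 against 31.8, and Hook1, Cdh19 and Fbxo21 with ratios of 1450 (400 to 11900), 3480 (625 to 138000) and 251 (69.3 to 2070). With counts summed per recipient the line-specific numbers were 469 higher in VQ-D1, 476 higher and 388 lower in VQ-D2, and 691 higher and 647 lower in VQ-D5.

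Tissue comparisons asked whether myeloma cells differ by site within a line. Few genes passed. Against bone marrow, no gene passed in spleen by edgeR, 829 had an unadjusted p under 0.05, DESeq2 called 41 and limma voom with recipient as a random block 9. In lymph node against bone marrow, 2 genes passed (886 unadjusted; 40 with DESeq2, 17 with the random block), among them Fcrla, a B lineage Fc receptor-like protein, lower by a log2 fold change of −1.37 (SE 0.208, adjusted p = 0.0105). In lymph node against spleen, 4 genes passed (651 unadjusted; 11 with DESeq2, 14 with the random block), among them Tubb6 at 1.22 (SE 0.2, adjusted p = 0.0251) and Anxa5 at 0.76 (SE 0.129, adjusted p = 0.0251) higher, and Cst3 at −0.50 (SE 0.0913, adjusted p = 0.05 after rounding) lower. In the order of these comparisons, 218, 264 and 179 genes passed without a filter on low counts and 4, 12 and 13 with recipient as a fixed block. With RLE scaling 3 genes passed in lymph node against spleen, 100% of them higher, against 75% with TMM. The Fcrla call ended without VQ-D4 replicate 1 (−1.34) or 4 (−1.21) and without VQ-D2 replicate 2 or 3 (−1.27 each). The Tubb6 call ended without VQ-D4 replicates 1, 3 or 4 (1.21, 1.26 and 1.15), any VQ-D2 replicate (1.14, 1.12, 1.23 and 1.07) or VQ-D5 replicates 1 or 4 (1.23 each). The Anxa5 call ended without VQ-D4 replicates 1, 3 or 4 (0.764, 0.746 and 0.717), VQ-D2 replicates 1, 2 or 4 (0.712, 0.803 and 0.664), VQ-D5 replicates 1 or 4 (0.747 and 0.708) or t-VK12653 replicate 2 (0.76). The Cst3 call ended without any single VQ-D2 or VQ-D5 library, VQ-D1 replicates 3 or 4, VQ-D4 replicates 1, 3 or 4, or t-VK12653 replicates 1 or 2, at values from −0.522 to −0.463, and with RLE scaling (adjusted p = 0.0513) or without abundant non-coding RNA (adjusted p = 0.0507). Without a donor line term the Fcrla, Tubb6, Anxa5 and Cst3 calls all ended (adjusted p = 0.417, and 0.343 for each of the other 3). The number of genes for spleen became 22 without VQ-D1 replicate 3, 15 without Control replicate 2, 6 without VQ-D1 replicate 4, 2 without Control replicate 3 and 1 without VQ-D2 replicate 1 or 2. For lymph node against bone marrow it became 7 without VQ-D1 replicate 3, 4 without VQ-D1 replicate 4 or VQ-D4 replicate 3, 1 without VQ-D2 replicate 2 or 3, and 0 without VQ-D4 replicate 1 or 4. For lymph node against spleen it became 0 without VQ-D4 replicate 1, 3 or 4, 1 without VQ-D2 replicate 1, 2 or 4 or VQ-D5 replicate 1, and 2 without VQ-D2 replicate 3, VQ-D5 replicate 4 or t-VK12653 replicate 2. Neutrophil genes were lower by camera in spleen (adjusted p = 2.85e-19) and lymph node (adjusted p = 3.24e-10) than in bone marrow, with adjusted p = 0.269 and 0.475 with an estimated correlation. Of 17 such genes none passed over all genes, and 17 and 14 were lower adjusted over the list alone. Cell cycle genes had a median of 0.22 in spleen against bone marrow, with 0 of 32 past the threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 1.64e-10, adjusted p = 0.445 with an estimated correlation). That call ended without a donor line term (adjusted p = 0.258).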

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

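Tests on neutrophil and B cell RNA, on the endothelial source of Cdh5, and on parts of chromosomes, gene properties and copy number were chosen only after the results were seen (parts of chromosomes in 3 forms: their direction, intervals judged for pairs grouped by size of shift, which left a few regions open in both groups, and intervals judged per pair, given here), while the rotation test was written before its result.

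Of 185 groups of 4 libraries tested, 19 held a library far from the other 3 by Dixon's gap over range at its 95% critical value. Chance gives about 1 in 20 for independent groups of like, normal values. The groups here overlap, since Cdh5 is a member of the endothelial sum, and libraries of a line differ in tissue. The flagged share is above 1 in 20, but for these reasons it cannot be judged against chance. In VQ-D4, replicate 1 had 78.7 CPM of summed neutrophil genes (next 15.9) and 12.8 CPM of Etv4 (next 15.9). In replicate 2, from liver, summed endothelial and stromal genes reached 748 CPM (next 48.8), Cdh5 733 (next 0.754) and Ptprc 10 (next 1.92). Replicate 3 of that line had 1680 CPM of Myc (next 1310) and 1150 of H2-K1 (next 722). Replicate 4 had 7.67 CPM of summed megakaryocyte, mast cell and basophil genes (next 14.8). In VQ-D1, replicate 1 had 117 CPM of Egr1 (next 36.9), 721 of Fos (next 168) and 36.2 of Xist (next 6.75), and replicate 3 had 828 of Igj (next 622). In VQ-D2, replicate 2 had about 17200 genes with a count (next 14400) and 45.0 CPM of Prkaa2 (next 33.4). In VQ-D5, replicate 1 had 12.9 CPM of Ezh2 (next 24.5), replicate 2 had 11.7 of Cd74 (next 4.77) and 87.1 of Xist (next 5.26), and replicate 4 had 44.0 of Ptpn13 (next 65.5). In t-VK12653, replicate 3 had 35.9 CPM of Nxf3 (next 42.8).

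Cdh5, an endothelial cadherin, was at 732.8 CPM in the single liver library of VQ-D4. Endothelial cells in that library are a candidate source. The highest of Kdr, Pecam1 and Emcn there was 1.29% of Cdh5 (0.1545, 9.43 and 0 CPM), and 1 of 13 other endothelial and stromal genes exceeded the other VQ-D4 libraries. The bound set against this source was 1%, so the source stays open by that bound, although most of its markers were low. Dll4 (287.5 CPM) and Cntn5 (171.8 CPM) were also high in that library alone, and no biological explanation was tested, since 1 library came from liver.

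Neutrophil and B cell genes were lower in tumour libraries than in controls, and RNA of those cells in the control sort is a candidate explanation. Within tumour lines, where plasma cells come from the same donor, 100% of the neutrophil list was lower in spleen and in lymph node than in bone marrow, with medians of −3.15 and −4.08, as RNA from marrow neutrophils would give. That test compared no control library. It speaks for neutrophil RNA in tumour libraries from bone marrow and leaves the source in the controls open. For B cells the test could not decide: the ratios of pairs among the 6 most abundant B cell genes varied by a median of 1.85 times over the 3 controls, between the bounds set. Summed B cell genes were 1394, 1906 and 1678 CPM in the controls, beside 3337, 9271 and 3783 CPM of neutrophil genes. The sort for CD138 would remove most neutrophils and the gate against B220 most B cells, and lower B cell identity in the tumours stays open as the biological reading.

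Median log2 differences of a chromosome's genes from the other tumour lines were highest in size for chromosome 7 (0.79 over 758 genes) and chromosome 14 (−0.73) in t-VK12653, chromosome 5 in VQ-D4 (−0.69) and chromosome 8 in VQ-D1 (−0.61). The test set beforehand singled out no chromosome: 405 of 1000 rotations of the boundaries gave a largest shift as large as the observed 0.789, and 0 of 100 pairs of line and chromosome passed, so chance placement of long co-regulated stretches is not excluded, although rotated blocks keep such stretches whole and separate them from chromosomes poorly. A second definition, chosen after the first failed and the values were seen, took the 22 pairs shifted by 0.25 or more, of which 16 had all 4 parts of the chromosome, by gene order, beyond 0 in the direction of the whole by a 95% bootstrap interval over blocks of 10 neighbouring genes (weakest part 95.2% of the whole for chromosome 5 in VQ-D5 and 94% for chromosome 7 in t-VK12653, but 38% for chromosome 3 in VQ-D1, with a lowest bound of 0.0206), which argues against a few regions in those 16, though narrowly in that pair and for chromosomes 10 and 4 in t-VK12653 (bounds 0.032 and 0.0403). In 4 pairs 3 parts and in 2 pairs 2 parts did, such as chromosome 14 in t-VK12653 (weakest part 69% of the whole) and chromosome 3 in VQ-D5 (−22.4%), so a few regions stay open there, while 102% of the median shift was left after regression on length, GC content and level. In 100% all 4 libraries had the line's direction, which copy number would give but so would any cause shared by a line, and different chromosome copy number may be followed up with DNA. The pairs were picked by medians that their parts make up, which draws the parts toward the shift. The intervals were not adjusted over parts or pairs, so the case against a few regions is limited. Each shift is taken against the mean of the other tumour lines, so the 22 pairs are not independent. Chromosome 5, for example, was at −0.581 and −0.693 in VQ-D1 and VQ-D4, and at 0.541 and 0.571 in VQ-D2 and VQ-D5.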

How the results depend on the processing

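Fits without abundant non-coding RNA, with VQ-D1 replicate 1 and VQ-D4 replicate 2 left out together, and within single lines were chosen after seeing the data, as was the attention to Control replicate 2, one of the planned left-out libraries. Over all alternatives, 581 counts of genes stayed within 1.5 times and 52 moved. Of values for gene lists, 4426 kept direction and side of the threshold, 366 lost the call and 14 reversed. For named genes the numbers were 3305, 65 and 0, and 2 gained a call. With an estimated correlation 0 of 168 list calls held. The cause of these changes was not tested.

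Tissue counts depended most on the processing (in the order spleen against bone marrow, lymph node against bone marrow, lymph node against spleen). DESeq2 gave 41, 40 and 11, no filter 218, 264 and 179, limma voom with recipient as a random block (correlation 0.205) 9, 17 and 14, and recipient as a fixed block 4, 12 and 13. Without a donor line term both lymph node counts were 0. Leaving out 1 library gave 0 to 22, 0 to 7 and 0 to 5. Without a donor line term these lists reversed: MYC targets (adjusted p = 0.879) and ribosomal proteins (0.72) in spleen against bone marrow, p53 targets in lymph node against bone marrow (0.162), and cell cycle (0.000187) and p53 targets (0.515) in lymph node against spleen. Cell cycle genes in lymph node against bone marrow reversed without VQ-D4 replicate 1 (adjusted p = 0.981; over all left-out libraries 0.00569 to 0.981). Stress genes in spleen against bone marrow reversed without VQ-D4 replicate 3 (adjusted p = 0.517; over all left-out libraries 0.000213 to 0.985).

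Replicate numbers did not pair the libraries: over 55 pairs the correlations of deviations were −0.222 to 0.142, and 7 libraries correlated best with their own number. The replicate block gave 24, 5 and 1 genes for tissues, with adjusted p = 0.182 for Fcrla and 0.103 each for Tubb6, Anxa5 and Cst3. For VQ against control it gave 3949. That fit took single libraries as units in place of line sums, without a line term, so the unit changed along with the block. Lists reversed under the block were cholesterol synthesis (0.682) and erythroid genes (0.561) in spleen against bone marrow, and cell cycle (0.446), proteasome (0.957), glycolysis (0.957), high-risk orthologues (0.885) and endothelial genes (0.791) in lymph node against bone marrow.

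VQ against control gave 2027 genes in bone marrow alone (which has no VQ-D2 library), 7786 for the mean of 4 lines, and 1148 to 3713 leaving out 1 unit. DESeq2 gave 4274, of which 3129 were shared with edgeR, RLE scaling 2872, no filter 2665, no non-coding RNA 2971, and 3299 without the libraries left out together. Summed per recipient, VQ-D2 against VQ-D5 gave 3115 genes, and line-specific genes numbered 469 (VQ-D1 higher), 476 and 388 (VQ-D2 higher and lower), 691 and 647 (VQ-D5 higher and lower). Leaving out immunoglobulin segments changes nothing, since 0 are listed, and the clonality alternative was not run. At 1.5-fold and 2-fold the simulated VQ against control comparison recovered 0%, and no fit varied depth. Depth sets the floors of 0.108 to 0.305 CPM under which a gene without reads is not shown to be absent.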

Other observations

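Tests of X-linked genes and of splits of the samples were written before their results, and the tissue effects within single lines and the choice of genes in the first paragraph came after the data were seen.

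Several regulators of chromatin, survival and surface identity had unequal mean levels in the lines, given here as levels without a test. Ezh2, the PRC2 methyltransferase, was at 92.8 ± 10.2 CPM in VQ-D2 and 22.2 ± 6.24 in VQ-D5, against 1.86 ± 1.62 in VQ-D1 and 0.45 ± 0.612 in VQ-D4 (SD, n = 4 each) and 47.0 ± 11.7 in controls (SD, n = 3). Kdm6a, an X-linked histone demethylase, was at 0.989 ± 1.36 CPM in VQ-D1 and 23.6 to 56.0 CPM on average in the other VQ lines. Bcl2, an inhibitor of apoptosis, was at 506.2 ± 119 CPM in t-VK12653 and 151.4 ± 21.2 in controls, against 0.529 in VQ-D5, 1.11 in VQ-D2, 4.69 in VQ-D4 and 45.0 in VQ-D1, while Mcl1 lay between 444.4 and 669.8 CPM in all 6 groups. Tnfrsf17, which encodes the surface receptor BCMA, was at 111.0 ± 30.04 CPM in controls, 67.2 ± 13.1 in VQ-D5 and 5 to 17.4 in the other VQ lines. Ptprc, which encodes CD45, was at 204.0 and 194.7 CPM in VQ-D1 and VQ-D2 and at 3.53 and 2.62 in VQ-D4 and VQ-D5. The VQ-D4 mean was raised by its liver library, at 10 CPM with the next library at 1.92.

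Tissue effects within single lines were few. No gene passed by edgeR for spleen against bone marrow in VQ-D1 (596 at an unadjusted p under 0.05), and 1 passed in t-VK12653, Cd37 at −1.44 on the log2 scale (SE 0.216, adjusted p = 0.0468). The difference of that effect between these lines gave 0 genes by edgeR and 589 unadjusted, and other tools were not run on it. In VQ-D5, Tmed3 was lower in lymph node than in bone marrow, at −1.68 (SE 0.16, adjusted p = 8.38e-05). In VQ-D2, 6 genes differed between lymph node and spleen: Slc1a1, Cpd, Etl4, Hipk3 and Tubb6 were higher, at 5.83, 4, 3.47, 1.81 and 1.60, and Rps13 was lower, at −1.02.

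More X-linked genes than expected among line-specific higher genes was a hypothesis for all VQ lines, and Fisher's exact test (two-sided) gave a higher share with p under 0.05 in 1 of 4 lines, which argues against it. In VQ-D1 the share was 6.68% against 3.17% of tested genes (exact p = 8.77e-07, adjusted p = 3.51e-06), in VQ-D5 1.65% (exact p = 0.000751, adjusted p = 0.0015), in VQ-D2 2.28% and in VQ-D4 2.56% (adjusted p = 0.216 and 0.222). Against the other tumour lines, the median log2 difference of X-linked genes was 0.236 in VQ-D1 and −0.289 in VQ-D5. It was −0.117 in VQ-D2 and −0.027 in VQ-D4. Fisher's test takes genes as independent, so with such shared shifts its p-values are not firm.

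Other splits of the same libraries were fitted to see whether chance could give as many genes. For VQ against control, with donor lines and control mice as units, 1 of 35 splits, the real one, reached the real 3192 (highest other 11). That is the smallest share that 35 splits can give, and no adjustment was made over the comparisons split. It argues against chance but does not exclude it, since line sums pool 4 libraries and control units are single libraries. The other splits took libraries as independent units, although the 4 libraries of a line come from 1 donor and, by the recipient numbers, from 2 recipients. Taken that way, 1 of 35 splits, the real one, reached the real count for t-VK12653 against control and for each of the 6 pairs of VQ lines. That argues against chance for independent libraries but does not exclude it, and it does not address recipients. With recipients as units there are 3 possible splits for a pair of lines and 10 for t-VK12653 against control, and with donor lines 5 for VQ against t-VK12653, too few to exclude chance. The highest other split of libraries gave 4973 genes for t-VK12653 against control (real 7320). For the pairs it gave 0 for VQ-D1 and VQ-D2 (real 6601), 2777 for VQ-D1 and VQ-D4 (5307), 1 for VQ-D1 and VQ-D5 (7523), 4602 for VQ-D2 and VQ-D4 (7337), 10 for VQ-D2 and VQ-D5 (4970) and 4473 for VQ-D4 and VQ-D5 (7557). For VQ against t-VK12653, 1 of 100 splits of libraries reached the real 7870 (highest other 1478), and for line-specific genes 1 of 100 did in each line (1635 against 731, 1444 against 342, 2306 against 217 and 2189 against 201 for VQ-D1, VQ-D2, VQ-D4 and VQ-D5), with the same limit, and no splits of recipients were fitted. For spleen against bone marrow the splits decide nothing, since the real count of 0 is reached by 100 of 100 by construction (highest other 4). For the other tissue comparisons chance was not excluded: 36 of 100 splits reached the real 2 for lymph node against bone marrow (highest other 8), and 8 of 100 the real 4 for lymph node against spleen (highest other 8).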
